A study of Homo sapiens with 8 samples.

How the data were processed

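Gene expression was measured on 8 arrays, 4 of human endometrial stromal cells exposed to 10 µM tamoxifen for 48 h and 4 of the same kind of cells exposed to vehicle. The control samples are called untreated in their titles, and per the labels' protocols they received vehicle. The labels do not say whether the cells were a line or primary cells, nor whether the 4 samples of a group were separate cultures or donors. The p-values therefore measure only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was isolated with TRIzol and a spin column kit, and the cDNA was fragmented and labelled with biotin, so that each array holds 1 sample in 1 colour.

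The authors deposited 1 table of log2 expression values, with 1 column per array and 1 row per probe set. Per the submitters' processing notes the values came from RMA, the robust multi-array average, which subtracts background, normalizes quantiles between arrays and summarises the probes of each probe set. Its version, the software and the genome build are not given in the sources used here, so no coordinates are given. That the scale is log2 was taken from the values, which run from 2.41 to 13.2, and from RMA's usual output. RMA brings the arrays to a common distribution before summarising, so a change of total RNA per cell would not be seen, and the upper and lower ends of its range compress fold changes. The authors' normalization was kept.

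The table holds 29096 probe sets. Platform annotation gave exactly 1 gene symbol for 19460 of them, several for 1754 and none for 7882, which are unnamed here. Symbols were checked through the Entrez ID against the RefSeq gene table of assembly GRCh38.p14, used for names only. Of the probe sets with 1 symbol 19429 matched and 0 symbols needed an update. Where a gene had more than 1 probe set (769 genes) the one with the highest mean over the 8 arrays stood for it, which left 18417 genes. Genes that are linked to the Y chromosome or that report on X inactivation were tested but are not reported.

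The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options, statmod 1.5.0 for the robust alternative), with the group as the only term and no block. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05, and no filter on dim genes was applied. Fold changes are tamoxifen minus vehicle on the log2 scale. In all 37 gene lists were written before the data were examined, as were the design, the rule for named genes and the alternatives. The lists cover lipid metabolism (cholesterol synthesis, SREBP-controlled uptake, fatty acid synthesis, cholesterol efflux, lipid droplets), lysosome and autophagy, stress responses, the cell cycle, p53 and apoptosis, steroid receptors and their targets, decidualization, drug metabolism, inflammation, interferon, matrix, TGF-beta, WNT, immediate early genes, hypoxia, respiration, ribosomal proteins, markers of epithelial, endothelial, leukocyte, perivascular and stromal cells, and housekeeping genes as a sign of RNA quality. Each list was set against all other genes with camera at a preset correlation between genes of 0.01, adjusted over the 37 lists, and with an estimated correlation and fry beside it. Members were counted over all genes and adjusted over the list alone.

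The named genes are the 10 with the largest rise and the 10 with the largest fall among genes past the threshold whose groups did not overlap and whose higher group mean lay above the 40th percentile of gene means. Small RNAs, names of clones or open reading frames, pseudogenes marked as such in the reference, and Y-linked genes were passed over. At most 4 members of each list are named, those with the smallest p, and ESR1, ESR2, GPER1 and PGR are always given. The rule on dim genes passed over ABCA1 and PTPRC, which are named as list members. PMVK and MYLIP, the histone genes H1-5 and H2AC16, PLTP, APOC1, TTC39B and EEPD1 were singled out after their values were seen.

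The fit and the set tests were first tested on simulated data for this comparison, with 18417 genes, 200 of them changed, in 10 simulations. Changes of 0.3, 0.6 and 1 on the log2 scale were found in 70.4%, 99% and 100% of cases, and 5.43% of calls were false. A lysosome list shifted by 0.15 was found in 100% of simulations, and on average 0 unshifted lists were called. The simulated genes were independent of each other, so the simulations do not show how the set tests behave on correlated genes. Their errors were normal, with SDs drawn from the variance model that limma fitted. The simulations therefore cannot show whether that model holds for the real arrays. Alternatives were a fit with the replicate number as a block, renewed quantile normalization, arrays centred on their medians, the dimmest 40% of genes left out, a trended and robust variance model, array weights, the mean of a gene's probe sets, every probe set tested, no moderation of the variance, a threshold of 0.01, other set tests, and each array left out in turn. List counts without the vehicle replicate 2 array were added after seeing the data. No 2 arrays held identical values.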

Results

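Transcript levels were measured in human endometrial stromal cells, the fibroblast-like cells of the connective tissue in the lining of the uterus. The cells had been exposed for 48 h to 10 µM tamoxifen or to vehicle. Tamoxifen is a ligand of the estrogen receptors that can block or activate them depending on the tissue. Each group held 4 samples with 1 array each, numbered 1 to 4 within the group. The medians of all probe sets lay between 5.86 and 5.93 on the log2 scale, and the correlations between arrays lay between 0.997 and 0.999. The vehicle replicate 2 array stood apart from the others, with the highest median (5.93) and an SD of 0.103 from its group mean over genes, against 0.0696 to 0.0826 on the other arrays. The first principal component held 34.8% of the variance between the arrays. The number of arrays limits the precision of every value given here. The study has 1 comparison, of tamoxifen with vehicle, which asks which transcripts the compound changes in these cells.

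Tamoxifen raised FABP3 more than any other gene. FABP3, which encodes a cytosolic fatty acid carrier, went from 5.64 ± 0.0922 with vehicle to 8.15 ± 0.456 with tamoxifen (log2, SD, n = 4), a 5.69-fold rise in array signal. Its vehicle level was dim, below the 40th percentile of gene means (6.02), and signal over background was not analysed here. The other genes raised at least 2-fold were HMGCS1, the cytosolic HMG-CoA synthase of the mevalonate pathway (3.08-fold), DHCR7, a late enzyme of cholesterol synthesis (2.35-fold), DPP4, a cell surface peptidase (2.29-fold), and ACAT2, a cytosolic acetyl-CoA acetyltransferase (2.11-fold). Next in size, with pseudogenes left out, were CYP51A1, FDPS, MVD and SQLE, which act in cholesterol synthesis, and SCD, a fatty acid desaturase, with log2 rises of 0.99, 0.94, 0.91, 0.88 and 0.89 respectively. Among genes above the 40th percentile of mean expression the largest fall was that of HAS2, a hyaluronan synthase, which fell by 0.81 on the log2 scale from 10.37 ± 0.0597 to 9.56 ± 0.158 (SD, n = 4). The chemokine genes CCL2 and CXCL8 fell by 0.72 and by 0.64, and TNFSF4 and the growth factor receptor gene GFRA1 fell by 0.64 and by 0.58. HHIP, an inhibitor of hedgehog signalling, fell by 0.65 to a dim 5.53 with tamoxifen (log2). LIN7A, CCBE1, the tight junction gene CLDN1 and the urokinase gene PLAU fell by 0.56, 0.49, 0.49 and 0.49.

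In the limma fit 456 of the 18417 genes tested changed at an adjusted p under 0.05, of which 325 rose and 131 fell. Of the changed genes 71.3% were raised, and this share was 84.3% (327 raised and 61 lowered) when each array was centred on its median. With such centring and without vehicle replicate 2 it was 67.7%. Most changes were small, with a median absolute log2 fold change of 0.31 (1.24-fold) against a median SE of 0.0544. There were 39 genes raised and 7 lowered at least 1.5-fold, and 5 raised and 0 lowered at least 2-fold. The 4 tamoxifen values lay wholly above or below the 4 vehicle values for 453 of the 456 changed genes, which follows largely from their choice by p. The same held for 9.63% of all genes, where chance alone gives 2.86% on average, a share from which correlated genes can depart. The adjusted p in limma was 1.27e-05 for FABP3, 6.6e-06 for FDPS, 6.76e-06 for DHCR7 and 7.75e-05 for both HMGCS1 and HAS2. For the 10 falls named above, which leave out genes that were dim in both groups, it lay between 7.75e-05 for HAS2 and 0.00942 for TNFSF4. Leaving out 1 array at a time gave between 205 changed genes (without tamoxifen replicate 2) and 403 (without tamoxifen replicate 4), and the counts were 283, 232, 260 and 277 without tamoxifen replicates 1 and 3 and vehicle replicates 1 and 3. Without the vehicle replicate 2 array it was 355, of which 232 rose and 123 fell. Each of the 20 genes named in the paragraph above kept its call in all 8 of these fits, with no adjusted p above 0.0417 (TNFSF4).

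**Figure D1:**
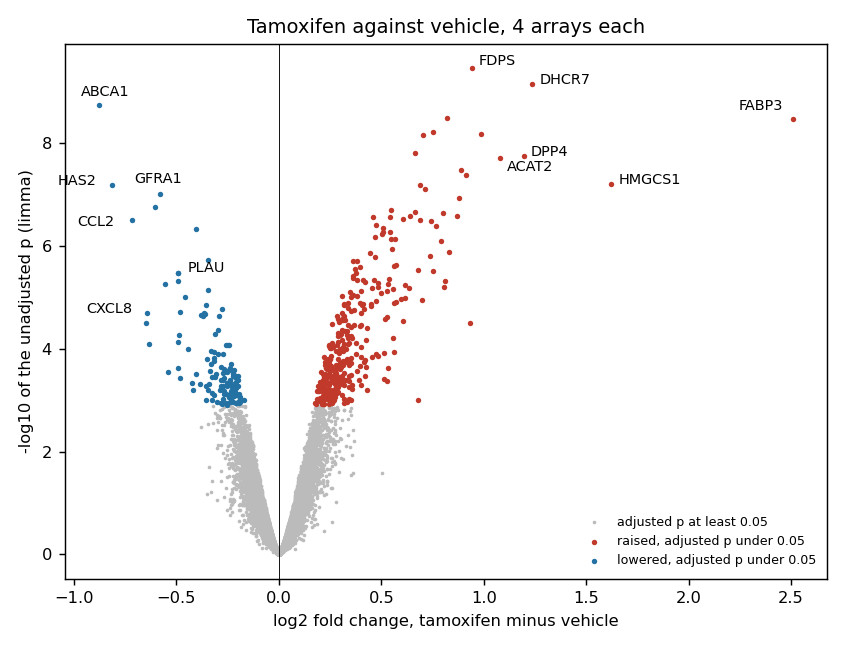
Each point is 1 gene, with the log2 fold change of tamoxifen over vehicle on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis (4 arrays per group). Genes at an adjusted p under 0.05 are coloured, 325 raised and 131 lowered, and FABP3 lies farthest to the right at 2.51.

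The cholesterol synthesis genes rose almost without exception. Of the 16 members analysed here, from a list of 20, 15 rose, and the count was also 15 when adjusted over the list alone. The median log2 fold change of the list was 0.82 (1.76-fold). The rise reached from the early steps, such as HMGCS1 (1.62 ± 0.14, SE), through FDPS (0.94 ± 0.0519), which makes farnesyl diphosphate, to later steps of the sterol branch, such as TM7SF2 (0.82 ± 0.0548), EBP (0.75 ± 0.0528) and DHCR7 (1.24 ± 0.0724). The exception was PMVK, which phosphorylates phosphomevalonate, at a log2 fold change of -0.05 and a limma adjusted p of 0.659. The mean of the list lay 0.79, 0.94, 0.98 and 0.62 above the vehicle mean in tamoxifen replicates 1 to 4, and within -0.03 and 0.05 of it on the vehicle arrays. By camera the list stood above all other genes (adjusted p = 9.41e-41), but the adjusted p was 0.0817 with an estimated correlation. The count of 15 was the same with any 1 array left out.

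**Figure D2:**
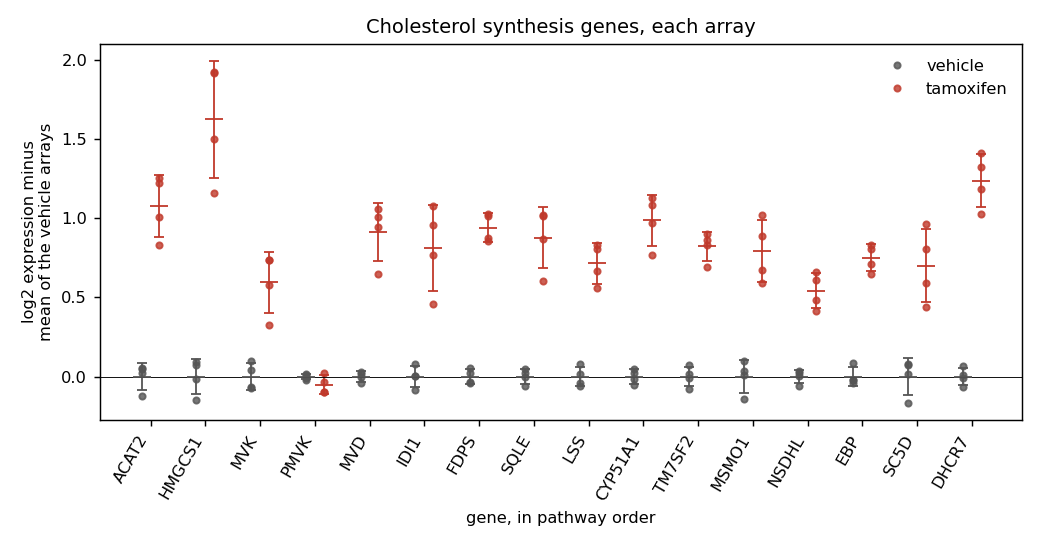
Each point is 1 array, and its height is the log2 expression of a cholesterol synthesis gene minus the mean of the 4 vehicle arrays (bars, mean ± SD, n = 4 per group; genes in pathway order). In every gene but PMVK the 4 tamoxifen arrays sit above the 4 vehicle arrays, with HMGCS1 highest at a mean of 1.62.

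Genes that control sterol uptake and the sterol response changed as well. Of 8 members analysed here, from 10, 5 rose and 1 fell. The rises included INSIG1 (0.74), which retains the SREBP complex in the endoplasmic reticulum, STARD4 (0.68), a sterol carrier, SREBF2 (0.67), which encodes the transcription factor SREBP2, and TMEM97 (0.64). MYLIP, a ubiquitin ligase that sends the LDL receptor to degradation, fell by 0.33. Adjusted over the list alone, 5 rose and 3 fell. The list passed camera (adjusted p = 5.28e-04, or adjusted p = 0.0817 with an estimated correlation). The limma adjusted p of MYLIP was 0.0366 and lost the threshold in 6 of the 8 fits with 1 array left out (highest 0.121), those without tamoxifen replicates 2, 3 and 4 and vehicle replicates 1, 3 and 4, and with the replicate block (0.0632). Without tamoxifen replicate 1 the list had 2 lowered members.

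Fatty acid synthesis and desaturation genes rose alongside. Of 10 members analysed here, from 11, 8 rose, and all 10 passed when adjusted over the list alone. The median log2 fold change was 0.47. The desaturase genes SCD, FADS2 and FADS1 rose by 0.89 ± 0.0726, 0.70 ± 0.05 and 0.47 ± 0.05 (SE), and ACSS2, which makes acetyl-CoA from acetate, rose by 0.83 ± 0.0946. The list passed camera (adjusted p = 2.96e-20, or adjusted p = 0.0817 with an estimated correlation). Among lipid droplet genes and targets of the peroxisome proliferator-activated receptors, 3 of 18 analysed here rose and 1 fell, and 3 rose and 3 fell when adjusted over the list alone. FABP3 led this group, followed by FABP4 (0.53) and the receptor gene PPARG (0.38), while G0S2, which encodes an inhibitor of triglyceride breakdown, fell by 0.24. The list did not pass camera (adjusted p = 0.444). FABP4 (limma adjusted p = 0.0263) lost its call in 6 of the 8 fits with 1 array left out, keeping it only without tamoxifen replicate 1 or vehicle replicate 4 (highest 0.0921), and G0S2 (adjusted p = 0.0171) lost it without tamoxifen replicates 1, 2 and 3 or vehicle replicate 3 (highest 0.0677).

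Among cholesterol efflux genes and targets of the liver X receptors, 2 of 8 analysed here fell, also when adjusted over the list alone, and none rose. ABCA1, the transporter that exports cholesterol from cells, fell by 0.88 from a dim 5.48 ± 0.0463 to 4.60 ± 0.105 (log2, SD, n = 4), and kept its call with any 1 array left out. LPCAT3, which remodels membrane phospholipids, fell by 0.24. The list did not pass camera (adjusted p = 0.197), and its median log2 fold change was -0.03. The call of LPCAT3 (limma adjusted p = 0.0467) held in only 1 of the 8 fits with 1 array left out, that without tamoxifen replicate 3 (highest 0.152), and was lost when arrays were centred on their medians.

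Lysosomal genes rose by smaller amounts. Of 22 members analysed here, from 25, 5 rose and 17 did not pass, and 16 rose and 1 fell when adjusted over the list alone. NPC1, which moves cholesterol out of the lysosome, rose by 0.69 ± 0.0686 (SE), the acid ceramidase gene ASAH1 by 0.57 ± 0.0813, the sialidase gene NEU1 by 0.49 ± 0.0644 and the hexosaminidase gene HEXA by 0.26 ± 0.0507. The list mean lay 0.13 to 0.23 above the vehicle mean on the 4 tamoxifen arrays. The list passed camera (adjusted p = 6.94e-13, or adjusted p = 0.0825 with an estimated correlation). The number of raised members was 3 without tamoxifen replicate 2, tamoxifen replicate 3 or vehicle replicate 4, each of which ended the call of HEXA (highest adjusted p in limma 0.0699). None of the 16 autophagy genes passed in limma, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 2 of them, led by WIPI1 (0.14, adjusted p = 0.202), and camera gave the list an adjusted p of 0.31.

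**Figure D3:**
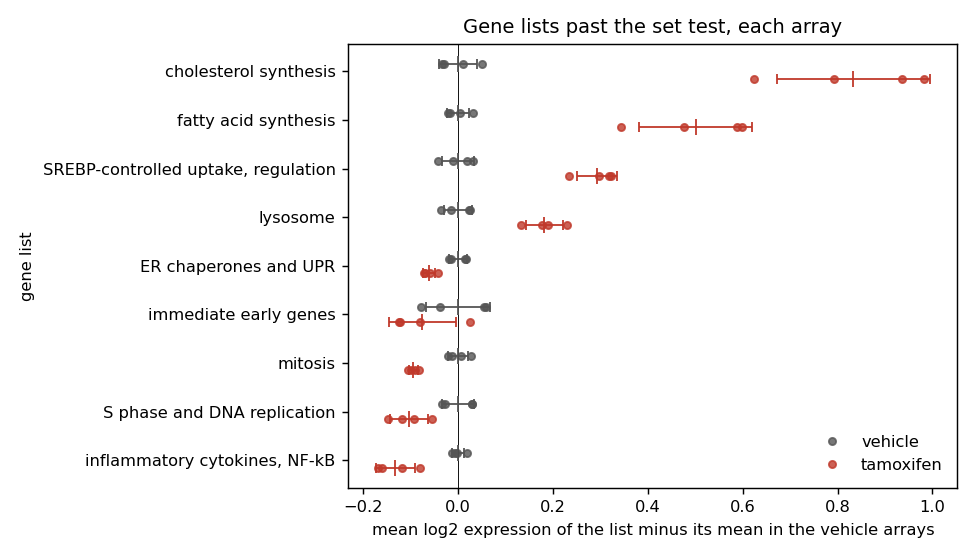
Each point is 1 array, and its position is the mean log2 expression of a gene list minus the mean of that list on the 4 vehicle arrays (bars, mean ± SD, n = 4 per group), for the 9 lists that passed camera. The tamoxifen arrays lie between 0.62 and 0.98 for cholesterol synthesis and between -0.11 and -0.08 for mitosis, and they overlap the vehicle arrays for the immediate early genes.

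Cell division genes shifted down by small amounts. Of 22 mitosis genes 1 fell, CDC20, an activator of the anaphase-promoting complex, by 0.22 ± 0.0427 (SE), and 2 fell when adjusted over the list alone. KIF20A, a mitotic kinesin, had a log2 fold change of -0.15 and a limma adjusted p of 0.0855. Of 20 S phase and DNA replication genes analysed here, from 21, 2 fell, and 6 fell when adjusted over the list alone. Both are subunits of the replicative helicase, MCM5 (-0.24 ± 0.0554, SE) and MCM2 (-0.19 ± 0.045). The lists passed camera, with an adjusted p of 8.67e-06 for mitosis and 7.63e-05 for S phase, and with median log2 fold changes of -0.11 in both. With an estimated correlation the values were adjusted p = 0.0825 and adjusted p = 0.303. The 3 single calls were lost when arrays were centred on their medians and with the replicate number as a block (limma adjusted p = 0.053, 0.0871 and 0.087). In limma fits with 1 array left out CDC20 lost its call without vehicle replicate 1 or 3 or tamoxifen replicate 2 or 3 (highest adjusted p 0.0822), MCM5 kept it only without replicate 4 of either group (highest 0.137), and MCM2 kept it only without tamoxifen replicate 4 (highest 0.152). Of 14 p53 target genes analysed here none passed in limma, 3 were at an unadjusted p under 0.05, and 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.864; GDF15 at 0.20, adjusted p = 0.0643). GDF15 passed without tamoxifen replicate 1 (limma adjusted p = 0.0397) and after renewed quantile normalization, and 1 other member fell without vehicle replicate 4. Of 13 apoptosis regulators 1 rose, the caspase inhibitor gene XIAP (0.20, adjusted p = 0.0296), also when adjusted over the list alone, but it lost its call in each of the 8 fits with 1 array left out (highest 0.114), with the replicate block (0.0817) and with the trended and robust variance model, and the list had a camera adjusted p of 0.948.

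Inflammatory cytokine genes and targets of NF-kB shifted down, mainly through a few members. Of 21 members 3 fell, the chemokine genes CCL2 (-0.72 ± 0.0718, SE) and CXCL8 (-0.64 ± 0.0957) and TNFAIP3 (-0.49 ± 0.0803), which encodes a feedback inhibitor of NF-kB. Adjusted over the list alone 4 fell. The median log2 fold change of the list was only -0.05, against a mean of -0.13, so its largest falls carried most of the shift. Most members were dim, and 8 of the 21 remained when the dimmest 40% of genes were left out. The list passed camera (adjusted p = 0.00116, or adjusted p = 0.0837 with an estimated correlation), and the count of 3 was the same with any 1 array left out. None of the 17 immediate early genes analysed here passed in limma, over all genes or adjusted over the list alone, and 3 were at an unadjusted p under 0.05, led by DUSP1 (-0.16, adjusted p = 0.219). The median log2 fold change of that list was -0.07, and it passed camera (adjusted p = 0.0212) but not with an estimated correlation (adjusted p = 0.659) nor in fry (adjusted p = 0.307). Its camera call was lost without tamoxifen replicates 1 and 3 and vehicle replicates 3 and 4, at adjusted p = 0.157, 0.141, 0.133 and 0.195. No interferon response gene of 20 passed in limma, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05, IFIT1 (-0.17, adjusted p = 0.107), and a camera adjusted p of 0.864.

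Genes of stress responses changed in small numbers. Of 18 genes of endoplasmic reticulum chaperones and the unfolded protein response 1 fell, SDF2L1 (-0.21 ± 0.0433, SE), and 5 fell when adjusted over the list alone. HYOU1, a chaperone of the same organelle, was at -0.21 with a limma adjusted p of 0.0582. The list passed camera (adjusted p = 0.0212, or adjusted p = 0.166 with an estimated correlation), with a median log2 fold change of -0.08. Its call was lost without vehicle replicate 1, vehicle replicate 3 or tamoxifen replicate 4 (adjusted p = 0.0747, 0.0586 and 0.0807), and SDF2L1 lost its own without tamoxifen replicates 1, 2 and 3 or vehicle replicates 1 and 3 (highest 0.0934), when arrays were centred on their medians and with the replicate block (0.0664). The heme oxygenase gene HMOX1 rose by 0.26 (limma adjusted p = 0.0102) as the single raised member of 13 NRF2 targets, also when adjusted over the list alone (camera adjusted p = 0.864). None of 20 ATF4 targets, 9 cytosolic heat shock genes, 8 metallothionein genes or 18 hypoxia and glycolysis genes passed in limma over all genes. At an unadjusted p under 0.05 there were 0, 0, 2 and 5 of them, and adjusted over the list alone 1 hypoxia gene fell and none of the others passed. Over all genes 1 hypoxia gene fell without vehicle replicate 1. The camera adjusted p was 0.864 for both ATF4 targets, where DDIT4 had the smallest p (log2 fold change 0.13, limma adjusted p = 0.393), and heat shock genes, and 0.223 for both metallothioneins and hypoxia.

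The receptors for estrogen and progesterone did not pass the test. The log2 fold change was 0.08 ± 0.052 (SE) for ESR1, -0.06 ± 0.0578 for ESR2, -0.02 ± 0.0416 for the membrane receptor gene GPER1 and 0.07 ± 0.0591 for PGR, with limma adjusted p values of 0.514, 0.692, 0.882 and 0.662. ESR1 and ESR2 were dim, at 4.85 ± 0.0603 and 3.96 ± 0.0771 with vehicle (log2, SD, n = 4), below the 40th percentile of gene means (6.02), while PGR was at 7.47 ± 0.0883. Of the 8 steroid and estrogen receptor genes analysed here, from 10, 0 were at an unadjusted p under 0.05, and none passed when adjusted over the list alone (camera adjusted p = 0.31). Of 15 estrogen receptor targets analysed here none passed in limma over all genes and 2 were at an unadjusted p under 0.05. Adjusted over the list alone 1 passed upward, CA12 (0.16 over all genes at adjusted p = 0.0611), and 1 downward, XBP1 (-0.18, adjusted p = 0.0654), and camera gave an adjusted p of 0.553. XBP1 passed over all genes when vehicle replicate 2 was left out (limma adjusted p = 0.0327) and in no other fit with 1 array left out. It also passed after renewed quantile normalization, with the dimmest 40% of genes left out, with the trended and robust variance model and with array weights. CA12 passed in the last 3 of these settings.

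Genes of decidualization, the conversion of these cells into the stroma of pregnancy, went in both directions. Of 22 members analysed here, from 25, 2 rose, the transcription factor genes FOXO1 (0.25 ± 0.0428, SE) and HAND2 (0.22 ± 0.0491). LTBP1 (-0.22) and IL11 (-0.24) were lower at limma adjusted p values of 0.0611 and 0.0612. Without tamoxifen replicate 4 IL11 passed (limma adjusted p = 0.017), and 1 member of the list rose and 2 fell. Adjusted over the list alone 3 rose and 3 fell, and camera gave an adjusted p of 0.864. FOXO1 kept its call with any 1 array left out (highest adjusted p 0.041 in limma), whereas HAND2 (adjusted p = 0.0389) lost its call in each of the 8 fits (highest 0.137), after renewed quantile normalization and with the replicate block (0.0631). Of 12 genes of the aryl hydrocarbon receptor and drug metabolism analysed here 1 rose, the epoxide hydrolase gene EPHX1 (0.21, adjusted p = 0.0285), and 2 rose when adjusted over the list alone (camera adjusted p = 0.444). EPHX1 kept its call only without vehicle replicate 3 or tamoxifen replicate 4 (highest 0.0948) and lost it with the replicate block (limma adjusted p = 0.0645).

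Genes of the matrix and of its turnover changed singly rather than as groups. MMP3, the stromelysin gene, rose by 0.55 ± 0.0526 (SE) and the gelatinase gene MMP2 by 0.20 ± 0.0433, while the plasminogen activator genes PLAU and PLAT fell by 0.49 ± 0.0615 and by 0.33 ± 0.0672. These 4 were the changed members among 17 matrix proteases and inhibitors analysed here, where 3 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.864). Of 20 matrix glycoproteins, proteoglycans and crosslinking genes 2 rose, LUM (0.25) and THBS2 (0.21), and 1 fell, POSTN (-0.23), against 3 and 3 when adjusted over the list alone (camera adjusted p = 0.553). Of 18 collagen genes 1 rose, COL11A1 (0.30), also when adjusted over the list alone (camera adjusted p = 0.663). Among 19 TGF-beta targets and myofibroblast genes analysed here TGFB2 rose by 0.32 and TAGLN fell by 0.24, against 2 and 1 when adjusted over the list alone (camera adjusted p = 0.444). Of 17 WNT pathway genes analysed here RSPO3 (0.33) and FZD4 (0.27) rose, also when adjusted over the list alone (camera adjusted p = 0.864).

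MMP3, PLAU and RSPO3 kept their calls with any 1 array left out. In limma fits with 1 array left out MMP2 kept its call only without tamoxifen replicate 4 and FZD4 only without vehicle replicate 4 (highest adjusted p 0.108 and 0.116). THBS2 and POSTN kept theirs only without vehicle replicate 2 or tamoxifen replicate 4 (highest 0.143 and 0.133), and COL11A1 only without vehicle replicate 1 or 2 or tamoxifen replicate 4 (highest 0.0921). PLAT and TAGLN lost theirs without vehicle replicate 1 or 3 or tamoxifen replicate 2 or 3 (highest 0.0921 and 0.0951), LUM without vehicle replicate 1 or 4 or tamoxifen replicate 2 or 3 (highest 0.0625), and TGFB2 without tamoxifen replicate 1 (0.0513). POSTN and TAGLN also lost their calls when arrays were centred on their medians, and MMP2, THBS2 and FZD4 lost theirs with the replicate block (limma adjusted p = 0.0706, 0.0597 and 0.0683).

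Markers of stromal cells were bright in both groups, and 3 of the 14 analysed here rose, also when adjusted over the list alone. These were MME, the CD10 gene (from 10.77 ± 0.0389 to 11.32 ± 0.122 in log2, SD, n = 4), LUM and HAND2, and the list had a camera adjusted p of 0.223. With 1 array left out at a time the number raised was 1 (without vehicle replicate 1 or 4 or tamoxifen replicate 2 or 3) or 2. Of 12 epithelial markers analysed here 1 fell, KRT18 (-0.30 ± 0.0538, SE, limma adjusted p = 0.0124), and 2 fell when adjusted over the list alone, with KRT19 at -0.17 (adjusted p = 0.0532). That list had a camera adjusted p of 0.112, and 0.0354 without tamoxifen replicate 4. Of 12 leukocyte markers 1 fell, also when adjusted over the list alone, PTPRC (-0.61 ± 0.0573, SE), a dim signal at 5.08 ± 0.078 with vehicle (SD, n = 4), while CD68 was at 0.12 (limma adjusted p = 0.226, camera adjusted p = 0.663). None of 10 endothelial markers (camera adjusted p = 0.223) or 10 perivascular and smooth muscle markers (0.864) passed in limma, over all genes or adjusted over the list alone, with 2 and 1 at an unadjusted p under 0.05. Of 14 long and short housekeeping genes, taken as a sign of RNA quality, none passed in limma either way and 1 was at an unadjusted p under 0.05 (camera adjusted p = 0.864), with MYCBP2 at 0.24 (adjusted p = 0.181). That list pools long with short genes, whose opposite shifts would cancel in camera, and long genes were not set against short ones. Its mean lay between -0.09 and 0.13 of the vehicle mean on the tamoxifen arrays, and between -0.05 and 0.04 on the vehicle arrays. Of 18 oxidative phosphorylation genes and 16 ribosomal protein genes analysed here none passed in limma over all genes, with 3 and 2 at an unadjusted p under 0.05, and 1 oxidative phosphorylation gene fell when adjusted over the list alone (camera adjusted p = 0.864 and 0.197).

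Of the 37 lists, 9 passed camera, 4 upward and 5 downward. With an estimated correlation 0 lists passed, although 7 had an unadjusted p under 0.05. In fry, which tests whether the genes of a list move 1 way on balance, 11 passed. These were the 9 lists except the immediate early genes, and also the cholesterol efflux and liver X receptor list (downward, adjusted p = 4.15e-04), the lipid droplet list (upward, adjusted p = 0.0016) and stromal identity (upward, adjusted p = 0.019). The median log2 fold changes of the lipid droplet and stromal lists were each 0.00.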

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

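The 4 values of each group were searched for an array far from the other 3, for the named genes, the array medians and the further genes described under the other observations. Of 178 such groups 10 held one, and chance alone gives about 5% of groups. CCL2 was at 7.96 in tamoxifen replicate 1, against 8.20 to 8.24 on the other tamoxifen arrays, and TGFB2 was at 7.57 there, against 7.43 to 7.45. TGFB2 lost its call without that array (adjusted p of 0.0513 in limma) and in no other fit with 1 array left out. Its log2 fold change stayed at 0.29 or higher in these fits, and several other named genes also lost their calls without that array. The median of all probe sets on the same array was 5.88, against 5.86 on each of the other 3. DPP4 was at 6.95 in vehicle replicate 1, against 6.65 to 6.68, GFRA1 at 9.86 there, against 9.90 to 9.91, and LIN7A at 7.25, against 7.48 to 7.49. ESR2 was at 3.75 in tamoxifen replicate 2, against 3.93 to 3.96, and PLTP at 9.22, against 9.29 to 9.30. LPCAT3 was at 10.12 in tamoxifen replicate 3, against 9.90 to 9.93, and TMEM97 at 9.91 in vehicle replicate 2, against 9.87 to 9.88.

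Signal was also found in probe sets outside the comparison of named genes. Of 9636 probe sets without a single gene symbol 20 differed between tamoxifen and vehicle at an adjusted p under 0.05 in limma, 16 higher and 4 lower with tamoxifen, and 685 at an unadjusted p under 0.05. Of these 20, 9 carry several gene symbols and 11 are unnamed here, so none is assigned to a gene.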

How the results depend on the processing

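All alternatives named here except the list counts without vehicle replicate 2 were fixed beforehand, and those counts were added after seeing the data. No called value changed direction. Of 1312 values of the 88 genes examined, 1147 kept their side of the threshold, 137 lost a call and 28 gained one. Of 555 values of the 37 lists 547 kept their side, 7 lost a call and 1 gained one. The direction of lists that do not pass is not called, and it flipped in 38 values. With 1 array left out the genes changed by tamoxifen ranged from 205 to 403, raised genes from 162 to 284, lowered genes from 43 to 123, genes changed at least 2-fold from 5 to 8 (8 without tamoxifen replicate 4) and lists past camera from 7 to 9. Raised genes were 162, 186 and 204 without tamoxifen replicates 2 and 3 and vehicle replicate 1. Lowered genes were 61, 43 and 46 without tamoxifen replicates 1, 2 and 3, and 56, 57 and 78 without vehicle replicates 1, 3 and 4. Of the 65 examined genes that passed, 43 did so in all 8 of these fits and 22 lost the call in at least 1. Without moderation of the variance 136 genes passed (96 raised, 40 lowered), and at an adjusted p under 0.01 there were 170 (139 raised, 31 lowered), the threshold itself being the cause. Lowered genes numbered 61 with arrays centred on their medians. Centring shifted the log2 fold changes of all genes upward alike, and their median went from -0.01 to 0.0091, which makes falls smaller. The low count of falls also depended on 1 array. With centring and without vehicle replicate 2, 241 of 356 changed genes rose (67.7%), against 78.73% to 87.22% with any other array left out. Lowered genes numbered 212 with the trended and robust variance model and 201 with array weights, where the cause was not tested. Other changed counts were 388 (centred), 521 (renewed quantile normalization), 584 (dimmest 40% left out), 621 (trended and robust), 577 (weights) and 452 (mean of a gene's probe sets). Over every probe set 368 passed. With an estimated correlation 0 lists passed and in fry 11 did. Camera's preset correlation is lower than most estimated ones, such as 0.68 for cholesterol synthesis. But the estimate was -0.03 for the SREBP list and 0.0101 for the chaperone list, and both lost their calls. A higher correlation thus does not account for every loss, and the cause was not tested. Without vehicle replicate 2, lowered S phase genes went from 2 to 0, raised lysosome genes from 5 to 4 and lowered chaperone genes from 1 to 2. Deviations from the group means in samples with the same replicate number correlated at 0.0137, -0.0823, 0.147 and 0.177, and not every sample correlated best with its own number, so the numbers were not taken to pair the samples. With the replicate block 332 genes changed, 312 of them shared, of which 245 rose and 87 fell, and 9 lists passed. Signal over background was not analysed here, so the limit that dim signal sets is known only from the counts with dim genes left out.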

Other observations

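The tests of array scaling and of shares with a further array left out, both tests on the histone genes and the test on further liver X receptor targets were chosen only after the result each bears on had been seen. Histone genes, which were in no list, were lower with tamoxifen as a class. Of 57 replication-dependent histone genes, which are transcribed mainly in S phase, 55 had a negative log2 fold change and 9 fell, with a median of -0.16 (95% bootstrap interval over genes -0.19 to -0.13). H1-5 fell by 0.32 (limma adjusted p = 0.0156) and H2AC16 fell by 0.28 (adjusted p = 0.00296). The call of H1-5 was lost without tamoxifen replicate 1, 2 or 3 (highest adjusted p 0.0566). As a set chosen after its values were seen, it had an unadjusted p of 1.55e-20 in camera, of 0.0306 with an estimated correlation and of 0.00288 in fry. The median of 7 replication-independent histone genes was -0.08, with an interval of -0.14 to 0.03. That median was -0.05 without tamoxifen replicate 1 and -0.04 after renewed quantile normalization. The median of the replication-dependent genes lay at -0.16 after renewed quantile normalization and at -0.14 after centring arrays on their medians, and the number lowered was 2 without tamoxifen replicate 3, 3 without tamoxifen replicates 1 and 2 and vehicle replicate 1, 5 without vehicle replicates 3 and 4 and after centring, and 6 without vehicle replicate 2.

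Most replication-dependent histone transcripts carry no poly(A) tail, so a lower yield of such RNAs in the tamoxifen samples was weighed first. If such RNAs were all lost alike, which was not tested, others without a tail would fall by about as much. The median of 195 snoRNA, snRNA and scaRNA genes was only -0.04 (-0.06 without vehicle replicate 2 and -0.02 without vehicle replicate 3), but as a class these were dim. Among the 84 above the 40th percentile of gene means the median was -0.1171 (bootstrap interval over genes -0.16 to -0.09), against -0.16 (-0.22 to -0.15) for the 45 histone genes above it. The intervals overlap, so a lower yield stays open. Fewer cells in S phase may be another candidate, as the S phase and DNA replication list, which holds no histone, had a median of -0.1093 (interval -0.15 to -0.04) and an unadjusted p of 0.00724 in fry but of 0.0655 with an estimated correlation. Signal shared between near-identical histone copies stays open, since 1 change of an abundant copy could then appear in many of the 57 genes, and cell cycle phase itself was not measured.

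ABCA1, LPCAT3 and MYLIP, all known targets of the liver X receptors, fell by 0.88, by 0.24 and by 0.33, which raised the hypothesis of a lower activity of these receptors, and this would lower other targets too. Of 5 further targets 4 were analysed here, PLTP (0.19), APOC1 (0.36), TTC39B (0.16) and EEPD1 (0.16), and all 4 had a positive log2 fold change, with a median of 0.1732 and an unadjusted fry p of 0.00322. None passed singly over all genes in limma (adjusted p = 0.13, 0.175, 0.238 and 0.21), though APOC1 did without tamoxifen replicate 4 (adjusted p = 0.0468). APOC1 and TTC39B were dim, below the 40th percentile of gene means, and with 1 array left out their values fell as low as 0.22 and 0.10, but the median stayed at 0.12 or higher. The planned list went the other way, with 2 of 8 positive, a mean of -0.13 and an adjusted p of 4.15e-04 downward in fry. But it holds ABCA1 and LPCAT3, which raised the hypothesis, and its median was only -0.03, so its fall is not separate support for the hypothesis. The only other members of that list that were not dim, SMPDL3A and APOE, stood at 0.11 and 0.07. The values thus argue against a loss at all targets, while a loss at some of them stays open.

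More genes rose than fell, and 3 explanations for the unequal split of 325 and 131 were tested against a bound of 60% raised. After renewed quantile normalization, the scaling with the lower share, 67.56% of changed genes were raised (95% exact binomial interval 63.4 to 71.6). Without the vehicle replicate 2 array the share was 65.35% (60.2 to 70.3), and outside the cholesterol, SREBP, fatty acid and lysosome lists it was 69.19% (292 of 422, interval 64.6 to 73.6). These intervals ignore correlation between genes and the second clears the bound by little. With any 1 further array left out the lowest shares were 65.98%, 62.09% and 62.11%, which argues against scaling and against the vehicle replicate 2 array as the whole cause. The lists hold too few genes to bring the share down to the bound, as 422 of 456 changed genes lay outside them. That share thus shows only that their own members are not the whole cause, and related genes outside the lists were not removed. With the dimmest 40% of genes left out 398 rose and 186 fell (68.2% raised), so falls hidden among dim genes do not account for all of it either, and its cause stays open.

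The 8 arrays can be split into 4 and 4 in 35 ways. For the number of genes changed, 1 of 35 splits, the real one, reached 456, and the highest of the others gave 0. The same held for raised genes (1 of 35, 325 against 0) and for lowered genes (1 of 35, 131 against 0). It also held for genes changed at least 2-fold (1 of 35, 5 against 0). These counts come from 1 comparison, and 1 of 35 is the smallest share the splits can give. Every other split put tamoxifen arrays on both sides, so a treatment effect would itself widen the spread there and lower the counts. Only the real grouping of these arrays reached the counts, but the gap to 0 in the other splits does not measure how far they lie from chance. Chance differences between cultures cannot be excluded, as the samples may be technical repeats. For the number of lists past camera 2 of 35 splits reached the real value of 9, with 9 the highest of the others, so chance cannot be excluded for that count. The other split set tamoxifen replicates 1, 2 and 3 and vehicle replicate 2 against the rest and so kept most of the real contrast. In the 18 splits with 2 tamoxifen arrays on each side the median was 1 list and the highest 3.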
